A study of Mus musculus with 9 samples.

How the data were processed

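Total RNA from dorsal pancreatic epithelium of mouse embryos was amplified, labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. The 9 arrays were grouped by the genotype in their labels into Sox9-het, Pdx1-het and double-het, 3 arrays each, and numbered as their labels number them. The deposited value table holds normalized intensity values on a linear scale, rounded to whole numbers, which the authors had already brought to nearly equal quartiles. The normalization, the background correction and the rule that left 1 probe per Entrez gene are not given in the sources used here. The submitters' processing notes name limma, with no version. A further table of the authors holds log2 ratios of double-het over each single heterozygote, per the file headers, with p-value columns given as an FDR per comparison and their product. It also holds signed folds and a score that equals the product of both log2 ratios, per the file headers and the deposited values. That table has 9 per-array columns whose headers name 3 slides but no sample of this series, and these were not used here. Slide and scan could therefore not be tested as batches. The table gives no detection flags, so which probes stand above background is not known here.

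Intensities of 18541 probes, 1 per Entrez ID, were taken to log2 with no further normalization, floor or filter. Symbols were updated through the Entrez ID with a RefSeq gene table of assembly GRCm38.p6, which matched 17183 probes and changed the symbol of 4384, among them Pdx1, listed under an older name. The other probes kept the name in the file, and no coordinates of that table are printed. A probe was classed as RefSeq (13687), cDNA clone (3030) or other (1824) by the accession the authors' annotation gives it.

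The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with default settings), and p was adjusted over all probes by Benjamini and Hochberg, with a threshold of 0.05. The contrasts were double-het minus Sox9-het, double-het minus Pdx1-het, Pdx1-het minus Sox9-het, and double-het minus the mean of both single heterozygotes. Group levels are means ± SD of the intensity over 3 arrays, and log2 differences are differences of mean log2 values. An exact permutation test of 3 against 3 arrays cannot give a p under 0.1.

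Named genes were Sox9 and Pdx1, the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap and whose mean lay above the 25th percentile of probes, members of each gene list past the threshold up to 4, up to 2 members with the largest statistic where none passed, and the 10 genes with the largest smaller statistic over both double-het contrasts. Clone, RIKEN, Gm and LOC names were left out except in the last part. Directions with fewer than 6 genes were to be filled to 6 from genes that did not pass, which was not needed.

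The 26 gene lists, of 7 to 29 measured genes, covered pancreatic progenitor factors, endocrine lineage factors, hormones and secretory granule, acinar and tip, duct and trunk, intestinal identity, stomach and anterior foregut, hepatic, Notch, FGF, Wnt, Hedgehog, BMP and TGF-beta signalling, cell cycle, p53 and cell death, epithelial, mesenchyme, mesothelium and spleen anlage, endothelium, erythroid, neural and neural crest, macrophage and immune, immediate early and stress, hypoxia and glycolysis, cartilage matrix genes and sex-linked genes. Each was tested with camera (preset correlation 0.01), adjusted over the lists within a comparison, beside camera with an estimated correlation and fry. The directional p of fry tests whether the genes of a list move, on balance, to one side, and neither it nor its mixed p compares a list with other genes.

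Overlaps between comparisons that share arrays were set beside 100 simulations of unchanged groups and beside the overlap of independent sets. Each simulation took as many rises and falls as limma had called, by rank of the statistic and whatever their p. It therefore does not show how many probes would pass the threshold in unchanged groups. Other splits of the arrays were counted, all 10 for 3 against 3 arrays and 100 drawn splits for all 9 arrays. Alternatives were the replicate number as a block, only the arrays compared, trend and robust eBayes, array weights, quantile normalization, centring on the 75th percentile, leaving out the 40% of probes of lowest mean, other thresholds (adjusted p under 0.1, unadjusted p under 0.05 with a fold of 1.5, treat with a fold of 1.2) and leaving out each array in turn. Limiting the probes to RefSeq accessions was added after the data had been seen. Where an array is left out, its group has 2 arrays and the spread is pooled over the groups.

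The procedure was tested on simulated data of 18541 genes, with 200 genes changed per comparison. The simulated noise was normal, independent between genes and of equal quality on all arrays, with each gene's moderated variance. The real arrays need not meet these settings, so the rates below hold for the simulation only. Of 100 genes changed by 0.5 on the log2 scale, 57% were recovered for double-het minus Sox9-het, 47% for double-het minus Pdx1-het and 55% for Pdx1-het minus Sox9-het, and of 100 changed by 1, 97% in each. False calls numbered 4, 7 and 10, and no recovered gene had the wrong sign. Figures were drawn with matplotlib 3.10.9.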

Results

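Dorsal pancreatic epithelium was dissected from mouse embryos at e12.5, and RNA pooled from 3 embryos per sample was hybridised to 1-colour Agilent expression arrays. The labels place the 9 arrays in 3 groups of 3, describe the groups as littermates and call the samples biological replicates. The group here called Sox9-het carried the Foxa3-Cre transgene and a floxed allele of Sox9, a transcription factor of pancreatic progenitors and ducts. The group called Pdx1-het carried a LacZ null allele of Pdx1, a homeodomain factor required for pancreas formation, and the group called double-het carried all of these alleles. No wild-type array was analysed here, so each comparison is between heterozygotes. The median intensity per array lay between 347 and 353 over 18541 probes, and the correlation of log2 values between replicates, taken across genes, which are not independent replicates, lay between 0.992 and 0.996. On the first principal component, which held 37.6% of the variance, double-het 3 stood at 36.9 and Sox9-het 1 at -25.4, outside the range of the other arrays. The title of double-het 3 names a pair of sample numbers. The number of arrays limits the precision of every value given here.

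Sox9 was not lower on the arrays labelled as carrying its deletion. Its intensity was 304 ± 17.9 (SD, n = 3) on the arrays labelled Sox9-het, 334 ± 44.8 (n = 3) on those labelled double-het and 224 ± 22.4 (n = 3) on those labelled Pdx1-het, which carry no Sox9 deletion by their label. The log2 difference of double-het minus Pdx1-het was 0.57 (SE 0.113, limma adjusted p = 0.108 over all probes and 0.00118 adjusted over the list alone, the list being Sox9 and Pdx1), and that of Pdx1-het minus Sox9-het was -0.45 (adjusted p = 0.298 and 0.00305). The Sox9 signal was thus higher on average in both groups labelled with its deletion, though neither difference passed over all probes. This signal alone does not decide whether the labels are right. The groups are called arrays labelled Sox9-het, Pdx1-het and double-het throughout. The position of the Sox9 probe relative to the deleted part is not known here, and a probe outside that part checks nothing. Pdx1 had an intensity of 1464 ± 133 (n = 3) on the arrays labelled Sox9-het, 1103 ± 26.4 (n = 3) on those labelled Pdx1-het and 1233 ± 108 (n = 3) on those labelled double-het. Pdx1 was thus lower on average in both groups labelled with its null allele. Its log2 difference was -0.40 for Pdx1-het minus Sox9-het (limma adjusted p = 0.217 over all probes and 0.00295 adjusted over the list alone) and -0.25 for double-het minus Sox9-het (adjusted p = 0.139 and 0.0459). With array weights these values of Pdx1 were -0.49 (adjusted p = 0.0103 over all probes) and -0.38 (adjusted p = 0.0117), in a fit where Sox9-het 2 had a weight of 9.12 against 0.478 and 0.925 for Sox9-het 1 and 3, so that the Sox9-het mean rested mostly on 1 array. The position of the Pdx1 probe relative to the disrupted part is not known here either. Foxa3, whose regulatory sequence drives the transgene, was 1006 ± 21.3 (n = 3) on the arrays labelled Sox9-het, 1101 ± 93.6 (n = 3) on those labelled double-het and 538 ± 14.8 (n = 3) on those labelled Pdx1-het, which carry no transgene by their label.

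**Figure D1:**
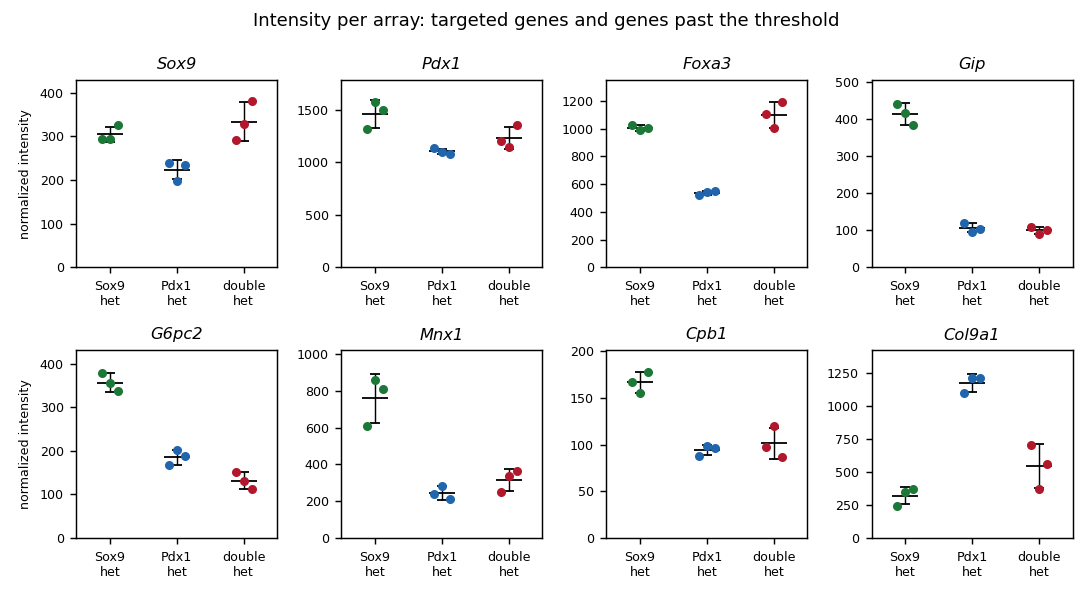
Normalized intensity (linear axis from 0) of 8 genes on each of the 9 arrays, grouped by label, with 1 point per array, a long bar at the mean and error bars of 1 SD. Sox9 is at 224 on average on the arrays labelled Pdx1-het and 304 on those labelled Sox9-het, and Gip is at 414 on the arrays labelled Sox9-het against 107 and 99.7 on those labelled Pdx1-het and double-het.

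Arrays labelled double-het and Sox9-het differ by label in the Pdx1 null allele alone. Gip, which encodes the incretin hormone GIP, fell from 414 ± 28.5 (n = 3) on the arrays labelled Sox9-het to 99.7 ± 10.1 (n = 3) on those labelled double-het, a log2 difference of -2.06 (SE 0.11, limma adjusted p = 0.00017). Its means on the arrays labelled double-het and Pdx1-het lay below the 25th percentile of probes, where the background is not known, so the size of the fall is uncertain. Also lower were G6pc2, the glucose-6-phosphatase subunit of islets (log2 -1.45, SE 0.117, adjusted p = 0.00362), Mnx1, a homeobox factor of the early dorsal pancreatic bud (-1.27, SE 0.177, adjusted p = 0.0294), and Adra2a, the alpha-2A adrenergic receptor (-1.64, SE 0.191, adjusted p = 0.0178). Dct, an enzyme of melanin synthesis, the short-chain fatty acid receptor Ffar2, the threonine dehydrogenase Tdh, Tmem171, Trim55 and Prickle2 fell by 1.36, 1.09, 0.98, 0.96, 1.03 and 0.87 on the log2 scale. Onecut2, a transcription factor of liver and pancreas development, rose from 205 ± 39.5 (n = 3) to 781 ± 378 (n = 3), a log2 difference of 1.85 (SE 0.273, adjusted p = 0.0341). Itih2, a plasma protein gene of the liver, rose by 1.40 (SE 0.216, adjusted p = 0.0386), and Krt19, a keratin of ducts, by 0.84 (SE 0.125, adjusted p = 0.0341). St8sia3, Pik3ap1, Tmprss6, Aldh1a7, Tmprss2 and Habp2 rose by 0.94, 0.90, 0.90, 0.89, 0.78 and 0.66. In all, 17 probes rose and 40 fell at an adjusted p under 0.05, and the 3 arrays of each label did not overlap for any of these 57. Over all probes, 35.3% had groups that did not overlap, where chance gives 10%, and 5071 (27.4%) had an unadjusted p under 0.05. The count was 13, 8 and 10 without Sox9-het 1, 2 and 3, 24, 11 and 23 without Pdx1-het 1, 2 and 3, and 4 and 24 without double-het 1 and 3. It was 3 when only the 6 arrays compared entered the fit, 3516 with array weights (of which Sox9-het 2 had 9.12) and 86 without the 40% of probes of lowest mean.

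Among the hormone and secretory granule genes, 25 were measured, G6pc2 fell and 24 did not pass, and 4 fell when adjusted over the list alone. The median log2 difference of the list was -0.20 (camera adjusted p = 0.00177, but adjusted p = 0.664 with an estimated correlation), and without double-het 2 the adjusted p was 0.0592 with a median of -0.13. Without Sox9-het 1 the median was -0.11. Of the 23 neural and neural crest genes, limma called 0, and 11 had an unadjusted p under 0.05. Adjusted over the list alone, 2 rose and 7 fell. Dcx, a microtubule protein of young neurons, had the largest statistic of the list and the opposite sign to its median, at 109 ± 4.7 (n = 3) on the arrays labelled Sox9-het and 152 ± 13.3 (n = 3) on those labelled double-het (log2 0.47, adjusted p = 0.0715). The Sox9-het mean of Dcx lay below the 25th percentile of probes, so the size of this difference is uncertain. Ednrb, the endothelin receptor of neural crest cells, was at 275 ± 6.6 (n = 3) on the arrays labelled Sox9-het and 209 ± 18.0 (n = 3) on those labelled double-het, and the list's median was -0.20 (camera adjusted p = 0.0167, but adjusted p = 0.664 with an estimated correlation, and 0.0529 without double-het 2). Hypoxia and glycolysis genes had the opposite sign. Pdk1, a kinase that restrains pyruvate dehydrogenase, was at 982 ± 55.3 (n = 3) and 1236 ± 39.5 (n = 3), limma called 0 of the 23 genes with 14 at an unadjusted p under 0.05, and 8 rose when adjusted over the list alone. Their median was 0.34 (camera adjusted p = 0.000381, but adjusted p = 0.664 with an estimated correlation), and 0.21 without double-het 3. Of 23 hepatic genes limma called 0, with 10 at an unadjusted p under 0.05. Adjusted over the list alone, 6 rose and 1 fell. The plasma protein gene Alb was at 332 ± 72.3 (n = 3) on the arrays labelled Sox9-het and 859 ± 277 (n = 3) on those labelled double-het. The hepatic median was 0.31 (camera adjusted p = 0.00177, but adjusted p = 0.664 with an estimated correlation, and 0.069 without the 40% of probes of lowest mean). FGF signalling genes had a median of 0.17, with 0 of 20 called by limma, 0 when adjusted over the list alone and 9 at an unadjusted p under 0.05. The camera adjusted p of the FGF list was 0.0411, but adjusted p = 0.664 with an estimated correlation, 0.0579 without Sox9-het 3, 0.109 without double-het 3, 0.127 with array weights, 0.295 without the 40% of probes of lowest mean and 0.0631 with RefSeq probes alone. Among 24 pancreatic progenitor factors Onecut2 rose, Mnx1 fell and 22 did not pass (adjusted over the list alone, 5 rose and 2 fell), and the list was not called (camera adjusted p = 0.179). Among 22 acinar and tip genes the digestive enzyme gene Cpb1 fell by 0.73 on the log2 scale (SE 0.117, adjusted p = 0.045), to a mean below the 25th percentile of probes, and 21 did not pass (adjusted over the list alone, 2 rose and 5 fell, camera adjusted p = 0.114). Array double-het 3, which stood apart on the first component, enters each of these differences.

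Arrays labelled double-het and Pdx1-het differ by label in the floxed Sox9 allele and the transgene. Foxa3, a forkhead factor of gut endoderm and liver, rose by 1.03 on the log2 scale from Pdx1-het to double-het (SE 0.077, limma adjusted p = 0.00366), a 2.04-fold difference. Its chromosomal neighbours Irf2bp1 and Mypop also rose, by 0.92 (SE 0.126, adjusted p = 0.0434) and 0.68 (SE 0.098, adjusted p = 0.0495). Upk3a, the serotonin transporter Slc6a4 and Serpina5 rose by 0.92, 0.81 and 0.67, Serpina5 from a mean below the 25th percentile of probes. Prickle2, a planar cell polarity gene, fell by 1.01 (SE 0.113, adjusted p = 0.0331), and Meis2, a homeobox factor, fell by 0.86 (SE 0.115, adjusted p = 0.0429). Trim55, Cdcp1, Fryl, Mapk8, Rian, Mmd2 and Kcna7 fell by 1.01, 0.81, 0.76, 0.75, 0.71, 0.67 and 0.60. In all, 7 probes rose and 13 fell at an adjusted p under 0.05, and the groups did not overlap for any of these 20. Over all probes 22.9% did not overlap, where chance gives 10%, and 2994 (16.1%) had an unadjusted p under 0.05. Of the 13 probes that fell, 9 (69.2%) were designed to cDNA clones, a class that makes up 16.3% of all probes, and with RefSeq probes alone, an alternative added after the data had been seen, the count was 1. The count was 2 without each Sox9-het array, 5, 1 and 4 without Pdx1-het 1, 2 and 3, 9, 4 and 6 without double-het 1, 2 and 3, 2 when only the 6 arrays compared entered the fit, and 59 without the 40% of probes of lowest mean.

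Hepatic genes lay higher on the arrays labelled double-het than on those labelled Pdx1-het. Alb was at 293 ± 50.0 (n = 3) and 859 ± 277 (n = 3), limma called 0 of 23 hepatic genes with 11 at an unadjusted p under 0.05, and 6 rose when adjusted over the list alone. The hepatic median was 0.28 (camera adjusted p = 1.32e-05, but adjusted p = 0.563 with an estimated correlation). Among 24 pancreatic progenitor factors Foxa3 rose and 23 did not pass, 5 rose when adjusted over the list alone, and the median was 0.18 (camera adjusted p = 0.00333, but adjusted p = 0.631 with an estimated correlation). The progenitor median was 0.11 with array weights and 0.08 without double-het 3. This list holds the targeted genes Sox9 and Pdx1, and Foxa3, whose regulatory sequence drives the transgene. It was not tested without them. For the other 8 lists called in this comparison limma called 0 genes, and each list had an adjusted p = 0.631 with an estimated correlation. Intestinal identity genes had a median of 0.16 (camera adjusted p = 0.00734, 0.0622 without double-het 3 and 0.11 without the 40% of probes of lowest mean), with 5 of 22 at an unadjusted p under 0.05 and 4 that rose when adjusted over the list alone. The intestinal median was 0.09 with array weights and 0.08 without double-het 3. Lgr5, a stem cell marker of the gut, was at 165 ± 6.1 (n = 3) and 257 ± 45.5 (n = 3). Acinar and tip genes had a median of 0.19 (camera adjusted p = 0.0151, 0.174 without Pdx1-het 2 and 0.404 without double-het 2), hypoxia and glycolysis genes 0.17 (0.0123, 0.506 without double-het 3 and 0.19 with array weights), and epithelial genes 0.12 (0.0303). The epithelial list was not called without double-het 1 (0.0653), Pdx1-het 2 (0.209) or double-het 3 (0.2), with array weights (0.0529), without the 40% of probes of lowest mean (0.142) or with RefSeq probes alone (0.118). The median of the acinar list was 0.06 without double-het 2. That of the hypoxia list was 0.06 with array weights and 0.02 without double-het 3, and that of the epithelial list 0.08 with array weights and 0.07 without Pdx1-het 2. At an unadjusted p under 0.05 there were 5 of 22 acinar, 3 of 23 hypoxia and 4 of 22 epithelial genes, and adjusted over the list alone 0, 1 and 0 rose. Such a p was found for 16.1% of all probes, so counts of this size say little about a list. Lower medians were found for endocrine lineage factors (-0.21, camera adjusted p = 0.00754, 0.167 without double-het 2 and 0.084 without Pdx1-het 3) and for hormone and secretory granule genes (-0.14, 0.0121, 0.405 without double-het 2, 0.0961 without Pdx1-het 3 and 0.11 without the 40% of probes of lowest mean). Pax6, an islet transcription factor, was at 1049 ± 93.8 (n = 3) on the arrays labelled Pdx1-het and 825 ± 87.5 (n = 3) on those labelled double-het. Neural and neural crest genes had a median of -0.16 (camera adjusted p = 0.00734, 0.0804 without Pdx1-het 3). Without double-het 2 the endocrine lineage median was -0.06 and the hormone median -0.02, and without Pdx1-het 3 the endocrine lineage median was -0.11 and the neural median -0.08. In each of these 3 lists 5 genes had an unadjusted p under 0.05, and adjusted over the list alone 0, 1 and 0 fell. Cartilage matrix genes, a list of genes that Sox9 binds, had a median of -0.13 (camera adjusted p = 0.0123), with 6 of 14 at an unadjusted p under 0.05 and 5 that fell when adjusted over the list alone. The cartilage median was -0.07 with array weights, -0.35 without the 40% of probes of lowest mean, -0.21 and -0.08 without double-het 1 and 3, and -0.20 with RefSeq probes alone.

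Arrays labelled Pdx1-het and Sox9-het compare the single heterozygotes with each other. Gip fell by 1.96 on the log2 scale on the arrays labelled Pdx1-het (SE 0.11, limma adjusted p = 0.000268), Mnx1 fell by 1.63 (SE 0.177, adjusted p = 0.0125) and Tdh fell by 1.37 (SE 0.093, adjusted p = 0.000781). Adra2a, Cela1, Ffar2, Egfl6, Dct, G6pc2, Eppin and Foxa3 fell by 1.65, 1.23, 1.14, 1.03, 1.01, 0.95, 0.91 and 0.90. The means of Gip, Eppin and Cpb1 on the arrays labelled Pdx1-het lay below the 25th percentile of probes, where the background is not known, and the size of these falls is uncertain. Genes of cartilage collagens rose. Col9a1 rose from 320 ± 66.2 (n = 3) on the arrays labelled Sox9-het to 1173 ± 68.2 (n = 3) on those labelled Pdx1-het, a log2 difference of 1.90 (SE 0.226, adjusted p = 0.0152), Col9a3 rose by 1.25 (SE 0.179, adjusted p = 0.0308) and Col2a1 by 0.82 (SE 0.086, adjusted p = 0.0104). Plekhb1, Sh3tc2, Mmd2, the chemokine receptor Cxcr4, Gsg1l, Zfp708 and the retinoid receptor Rxrg rose by 1.17, 0.94, 0.91, 0.79, 0.72, 0.66 and 0.61. Beside Sox9, the uncharacterised transcript 2610035D17Rik, named because it neighbours Sox9 and chosen after its values were seen, rose by 0.97 (adjusted p = 0.00193). In all, 15 probes rose and 28 fell at an adjusted p under 0.05, with no overlap between the groups for any of these 43. Over all probes 12.6% did not overlap, where chance gives 10%, and 1166 (6.29%) had an unadjusted p under 0.05. The count was 17, 8 and 10 without Sox9-het 1, 2 and 3, 11, 4 and 4 without Pdx1-het 1, 2 and 3, and 71 without double-het 3, which enters only through the shared spread. It was 227 with array weights, again with 9.12 for Sox9-het 2.

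Acinar and tip genes lay lower on the arrays labelled Pdx1-het. Of 22 measured, the elastase gene Cela1 and the carboxypeptidase gene Cpb1 fell (Cpb1 by 0.83 on the log2 scale, SE 0.117, adjusted p = 0.0288) and 20 did not pass, while 13 fell when adjusted over the list alone. The median of the acinar list was -0.41 (camera adjusted p = 9.02e-09, but adjusted p = 0.427 with an estimated correlation). Among 14 cartilage matrix genes Col9a1, Col9a3 and Col2a1 rose and 11 did not pass, and 4 rose when adjusted over the list alone. Their median was 0.08 and their mean 0.35 (camera adjusted p = 9.28e-05, but adjusted p = 0.427 with an estimated correlation). The cartilage median was 0.40 without the 40% of probes of lowest mean, 0.12 without Pdx1-het 1 or Sox9-het 3, and 0.14 with RefSeq probes alone. Of 20 macrophage and immune genes limma called 0, with 1 at an unadjusted p under 0.05, and 19 of the 20 had a negative log2 difference. The macrophage median was -0.18 (camera adjusted p = 7.42e-06, but adjusted p = 0.435 with an estimated correlation) and -0.11 with array weights, and the complement gene C1qc was at 1809 ± 231 (n = 3) and 1499 ± 86.6 (n = 3) on the arrays labelled Sox9-het and Pdx1-het. Limma called 0 genes of each of the other 4 lists called here, and 0 when adjusted over the list alone. With array weights the endothelial median was 0 and the immediate early median -0.06. The endothelial median was -0.07 and -0.20 without Sox9-het 1 and 2, and the FGF median 0.17 without Pdx1-het 1 and 0.06 without Sox9-het 3. Endothelial genes had a median of -0.11 (camera adjusted p = 0.00409, but adjusted p = 0.662 with an estimated correlation, 0.247 without Sox9-het 1, 0.138 without Pdx1-het 2 and 0.718 with array weights), with 1 of 20 at an unadjusted p under 0.05. Immediate early and stress genes had a median of -0.09 (0.00988, but adjusted p = 0.504 with an estimated correlation, 0.139 without Sox9-het 1 and 0.0591 without Pdx1-het 3), with 2 of 23 at an unadjusted p under 0.05. FGF signalling genes had a median of 0.11 (0.00409, but adjusted p = 0.49 with an estimated correlation and 0.127 without Pdx1-het 2), with 2 of 20 at an unadjusted p under 0.05. Hypoxia and glycolysis genes had a median of 0.13 (0.00437, but adjusted p = 0.662 with an estimated correlation, 0.0584 without Pdx1-het 2 and 0.0522 without Sox9-het 3), with 2 of 23 at an unadjusted p under 0.05. Among 25 hormone and secretory granule genes G6pc2 and the potassium channel gene Kcnj11 fell, the latter by 0.79 on the log2 scale (SE 0.112, adjusted p = 0.0288), 23 did not pass, 4 fell when adjusted over the list alone, and the list was not called (camera adjusted p = 0.0726). Among 24 pancreatic progenitor factors Foxa3 and Mnx1 fell and 22 did not pass (adjusted over the list alone, 2 rose and 5 fell, camera adjusted p = 0.164).

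Of the 26 gene lists, 14 were called in at least 1 of these 3 comparisons and 12 in none. Other splits of the same 6 arrays called lists too. With the real split included, 8 of 10 splits gave as many lists for double-het minus Sox9-het. For double-het minus Pdx1-het and for Pdx1-het minus Sox9-het, 3 of 10 did so. The number of lists called is therefore not particular to the labels. The uncalled lists were duct and trunk, stomach and anterior foregut, Notch pathway, Wnt signalling, Hedgehog signalling, BMP and TGF-beta signalling, cell cycle, p53 and cell death, mesenchyme, mesothelium and spleen anlage, erythroid and sex-linked genes. Their lowest camera adjusted p was 0.179, 0.281, 0.054, 0.276, 0.179, 0.253, 0.242, 0.0726, 0.391, 0.392, 0.0901 and 0.873 in that order. Krt19, in the duct and trunk list, was the only gene of these 12 lists that limma called. With an estimated correlation in place of the preset 0.01, camera called 0 of the 26 lists in each comparison (lowest adjusted p 0.427), and the directional test of fry also called 0 (lowest adjusted p 0.115). The mixed test of fry, which lets genes move to either side, passed for some lists and not for others. For double-het minus Sox9-het its adjusted p ran from 1.8e-05 (hormones and secretory granule) to 0.743 (sex-linked). It does not compare a list with other genes. In 6 cases, all of them uncalled, the sign of a list's median, mean and test was not the same.

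**Figure D2:**
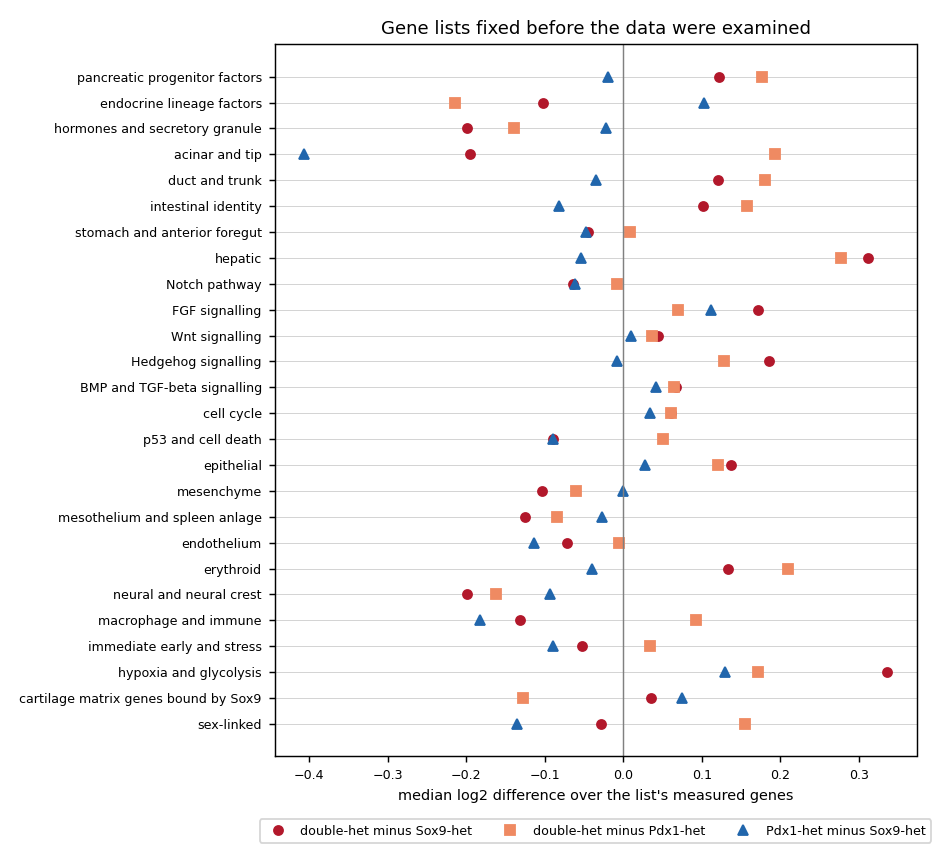
Median log2 difference over the measured genes of each of the 26 gene lists (horizontal axis, log2 scale), with circles for double-het minus Sox9-het, squares for double-het minus Pdx1-het and triangles for Pdx1-het minus Sox9-het. Hepatic genes are at 0.31 and 0.28 in the double-het comparisons, and acinar and tip genes at -0.41 in Pdx1-het minus Sox9-het.

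The series title asks for genes regulated by Sox9 and Pdx1 together, which the design addresses through genes that differ between double-het and each single heterozygote. Fryl, Mapk8, Prickle2, Kcna7, Cdcp1, Trim55, the imprinted long non-coding RNA Rian and 6820402I19Rik fell in both. Fryl was at 317 ± 10.5 (n = 3) on the arrays labelled Sox9-het, 339 ± 6.8 (n = 3) on those labelled Pdx1-het and 200 ± 9.0 (n = 3) on those labelled double-het, with log2 differences of -0.67 and -0.76 (SE 0.067, limma adjusted p = 0.00942 and 0.00745). Mapk8, the stress kinase JNK1, was at 1616 ± 146, 1534 ± 75.6 and 912 ± 69.1 (n = 3 each), and the potassium channel gene Kcna7 was at 316 ± 4.2, 328 ± 20.6 and 216 ± 10.6 (n = 3 each). Pdpk1, a kinase of insulin signalling, fell by 0.76 against Sox9-het (adjusted p = 0.029) and had a log2 difference of -0.64 against Pdx1-het that did not pass (adjusted p = 0.0713). Of the 9 probes that passed in both with the same sign, 5 were designed to cDNA clones (Fryl, Mapk8, Prickle2, Cdcp1 and 6820402I19Rik). With RefSeq probes alone limma called 0 in both comparisons, with 1244 at an unadjusted p under 0.05 in each and of the same sign. Independent sets of these sizes would share 0.0064 rises and 0.028 falls. In simulated unchanged groups on shared arrays, sets of the same sizes were taken by rank, whatever their p. These sets shared 4.59 probes on average and up to 20 in 100 simulations. An overlap of 9 lay inside that range. How many probes would pass the threshold in such groups was not simulated. The covariance of the log2 differences was 0.0387 against 0.0112 simulated (r of 0.73 against 0.454, across genes). The simulated mean already holds the sharing of arrays, but its spread is not given here. The double-het arrays could not be divided into parts of at least 2. Whether the excess lies beyond what shared arrays can give is therefore not known. The count of 9 was 1, 0 and 1 without Sox9-het 1, 2 and 3, 1, 0 and 3 without Pdx1-het 1, 2 and 3, and 1, 3 and 4 without double-het 1, 2 and 3. At the counts of 0, without Sox9-het 2 and without Pdx1-het 2, 1263 and 1179 probes had an unadjusted p under 0.05 in each with the same sign.

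**Figure D3:**
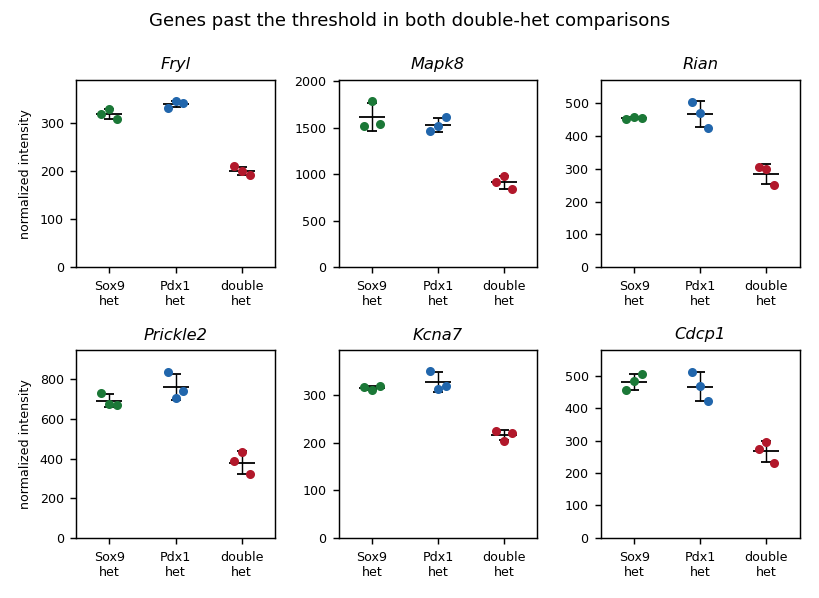
Normalized intensity (linear axis from 0) of 6 of the 9 genes that passed in both double-het comparisons, with 1 point per array, a long bar at the mean and error bars of 1 SD. Fryl is at 200 on average on the arrays labelled double-het against 317 and 339 on those labelled Sox9-het and Pdx1-het.

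Gip, G6pc2, Mnx1, Adra2a, Dct, Ffar2, Tdh and Cpb1 were lower on the arrays labelled Pdx1-het and on those labelled double-het than on those labelled Sox9-het. The comparisons with Sox9-het shared 16 probes of the same sign, 1 that rose (Habp2) and 15 that fell. Independent sets would share 0.014 and 0.06. Sets of the same sizes taken by rank in simulated unchanged groups shared 7.95 on average and up to 36. The covariance was 0.024 against 0.0128 simulated (r of 0.553 against 0.518, across genes). The simulated mean already holds the sharing of arrays, but its spread is not given here. Whether the excess lies beyond what shared arrays can give is therefore not known. Foxa3 and Slc6a4 were higher, and Mmd2 and 2610035D17Rik lower, on the arrays labelled double-het than on those labelled Pdx1-het, with the opposite sign in Pdx1-het minus Sox9-het. These 4 probes compare with 0.011 rises and 0.011 falls for independent sets. Sets of the same sizes taken by rank in the simulation shared 3.08 on average and up to 18. The covariance was -0.0061 against -0.0099 simulated (r of -0.166 against -0.422). The simulated opposition was stronger on average. Its spread is not given here, so whether the data differ from shared arrays alone is not known.

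Set against the mean of both single heterozygotes, the arrays labelled double-het had 4 probes that rose and 21 that fell. Tmprss6 and Foxa3 rose by 0.71 and 0.58 on the log2 scale (limma adjusted p = 0.0347 and 0.0178), and Gip, G6pc2, Trim55, Prickle2, Meis2 and Pdpk1 fell by 1.08, 0.98, 1.02, 0.94, 0.72 and 0.70. Against each single heterozygote, Foxa3 passed only from Pdx1-het (log2 0.13 from Sox9-het, adjusted p = 0.291) and Gip only from Sox9-het. The means of Gip on the arrays labelled double-het and Pdx1-het lay below the 25th percentile of probes, where a difference between them could go unseen. A total of 4953 probes had an unadjusted p under 0.05. The same contrast gave 50 probes for Sox9-het against the mean of the other groups and 22 for Pdx1-het. The count of 25 was 18, 3 and 2 without Sox9-het 1, 2 and 3, 17, 7 and 19 without Pdx1-het 1, 2 and 3, and 34, 15 and 10 without double-het 1, 2 and 3, and it was 466 with array weights (9.12 for Sox9-het 2), 208 without the 40% of probes of lowest mean and 12 with RefSeq probes alone.

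The authors' deposited table gives its own log2 ratios for both double-het comparisons, which equal the differences of mean log2 intensity to within 4.3e-08. The authors' deposited table has an FDR under 0.05 for 4292 probes against Sox9-het and 3199 against Pdx1-het, from a test not stated in the sources used here, and all 57 and 20 probes called with limma lie among them. In that deposited table of the authors, 1798 probes pass in both, 857 higher and 925 lower in double-het, and cDNA clone probes make up 44.9% of the lower and 7.35% of the higher ones. Prap1, chosen after its values were seen, has FDR values of 1.2e-10 and 1.81e-07 in the authors' deposited table. Its intensities on double-het 1, 2 and 3 were 10878, 869 and 457, against 190, 127 and 116 on the arrays labelled Sox9-het and 196, 301 and 236 on those labelled Pdx1-het, and its limma adjusted p against the mean of both was 0.0929.

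Of 68 named gene results that passed, all kept their direction in each alternative that kept their probe, which leaving out the 40% of probes of lowest mean did for 54 and RefSeq probes alone for 51. Those for Gip (against Sox9-het, in both groups), G6pc2 (double-het minus Sox9-het), Tdh (Pdx1-het minus Sox9-het) and Foxa3 (both comparisons with Pdx1-het), 6 in all, passed in each such alternative, Gip and G6pc2 being untested without the probes of lowest mean. With Dct (double-het minus Sox9-het), 7 passed whichever array was left out.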

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

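The limit to RefSeq probes was chosen only after the data had been seen, and the other alternatives were planned. Of 68 named gene results that passed, 6 passed in each alternative that kept their probe and 7 whichever array was left out, and all 68 kept their direction in these. Since their groups did not overlap, the direction was fixed except under quantile normalization and centring on the 75th percentile. Leaving out the 40% of probes of lowest mean kept 54 of the 68, without Gip and G6pc2, and RefSeq probes alone kept 51. Of 22 list calls by camera with the preset correlation, 7 passed in the alternatives of this section and 8 whichever array was left out, and 21 kept the sign of their median. With an estimated correlation none of the 22 passed (lowest adjusted p 0.427). No list that passed was reversed. Quantile normalization and centring on the 75th percentile left the median of all genes within 0.02 of 0 on the log2 scale.

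Of the probes past the threshold, the replicate number as a block gave 18 for Pdx1-het minus Sox9-het and 71 for double-het minus the mean of both single heterozygotes, and 22 of the 68 named gene results, among them Col9a1, Col9a3, Cela1, Cpb1 and Kcnj11 for Pdx1-het minus Sox9-het, no longer passed. With only the arrays compared, the double-het counts were 3 against Sox9-het, 2 against Pdx1-het and 0 in both by limma (1562 at an unadjusted p under 0.05), from a fit with fewer arrays. Array weights gave 3516 (double-het minus Sox9-het), 227 (Pdx1-het minus Sox9-het) and 466 (against the mean of both), and Pdx1 then passed with log2 differences of -0.38 for double-het minus Sox9-het and -0.49 for Pdx1-het minus Sox9-het. The weights ranged from 0.312 (double-het 3) to 9.12 (Sox9-het 2, against 0.478 and 0.925 for Sox9-het 1 and 3), so the Sox9-het mean of these fits rested mostly on 1 array. Without the 40% of probes of lowest mean the double-het counts were 86 against Sox9-het, 59 against Pdx1-het, 208 against the mean of both and 16 in both, and 3 lists passed for double-het minus Sox9-het. RefSeq probes alone gave 1 against Pdx1-het, 12 against the mean of both and 0 in both by limma (1244 at an unadjusted p under 0.05), with 11 lists for Pdx1-het minus Sox9-het. The cause of these moves was not tested.

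The counts followed the threshold. In the order double-het minus Sox9-het, double-het minus Pdx1-het, Pdx1-het minus Sox9-het, double-het minus the mean of both, and both double-het comparisons, an adjusted p under 0.1 gave 463, 78, 67, 1083 and 33 probes. An unadjusted p under 0.05 with a fold of 1.5 gave 322, 198, 130, 167 and 81. Limma's treat with a fold of 1.2 gave 3, 1, 5, 0 and 0, and the last 2 had 331 and 124 at an unadjusted p under 0.05.

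Leaving out 1 array in turn gave 4 (without double-het 1) to 68 (without double-het 2) probes for double-het minus Sox9-het, 1 (without Pdx1-het 2) to 9 (without double-het 1) for double-het minus Pdx1-het and 4 (without Pdx1-het 2 or 3) to 71 (without double-het 3) for Pdx1-het minus Sox9-het. It gave 2 (without Sox9-het 3) to 34 (without double-het 1) against the mean of both, and 4 (without Pdx1-het 2) to 10 (without Pdx1-het 1) lists for Pdx1-het minus Sox9-het. In both double-het comparisons it gave 0 (by limma, without Sox9-het 2 or Pdx1-het 2, with 1263 and 1179 at an unadjusted p under 0.05) to 4 (without double-het 3). The labels do not say that a number marks a litter, and the residuals of arrays with the same number correlated at -0.18 to 0.24, so the numbers were not taken to pair the samples. An array correlated best with its own number in 9 of 18 cases, and a shared litter behind some numbers is not excluded.

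Not run were another choice of probe per gene, since the table holds 1 probe per gene, the per-array values of the other deposited table, whose headers name no sample, and only the arrays compared for the contrast that uses all 9. No detection flags or background values were used here, so what low signal limits is known only from leaving out the probes of lowest mean.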

Other observations

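The genes of this paragraph were chosen after their values were seen, and no difference between single arrays was tested. Cdx2, a homeobox factor of intestinal epithelium, was at 85, 216 and 465 on double-het 1, 2 and 3, and at 67 to 94 on the 6 other arrays. Guca2b, which encodes uroguanylin, was at 2218 on double-het 1 and at 237 and 162 on double-het 2 and 3, and at 119 to 174 on the 6 other arrays. Neurog3, the factor that starts endocrine differentiation, was at 573, 412 and 255 on double-het 1, 2 and 3, at 684, 413 and 439 on the arrays labelled Sox9-het, and at 612, 673 and 732 on those labelled Pdx1-het.

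The tests of the neighbours of Foxa3 and of the hepatic genes, and the list of nuclear RNAs, were chosen only after the results were seen. The pattern of cDNA clone probes was noticed in the data and its other tests were chosen before they were computed.

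Clone probes made up 16.3% of all probes, 40.9% of the 986 that were lower in double-het at an unadjusted p under 0.05 in both comparisons, and 7.17% of the 865 that were higher. Matched on mean log2 value, clone probes lay at -0.159 relative to RefSeq probes in double-het minus the single heterozygotes, which argues against dim probes as the cause, and the matched difference of Pdx1-het minus Sox9-het was 0.007. Relative to RefSeq probes they lay at -0.105, -0.118 and -0.217 on double-het 1, 2 and 3, and the smaller value of the other arrays, -0.105, argues against double-het 3 alone. Unspliced or nuclear RNA in unequal amounts between preparations may explain this, but its test is void, since only 71.7% of clone probes had a gene length (Spearman rho with gene length -0.085 among clone probes and 0.063 among RefSeq probes). All 8 measured of 10 listed nuclear RNAs had negative log2 differences in both comparisons, and only Rian passed. Against Sox9-het and Pdx1-het the differences were small for Mirg (-0.058 and -0.116) and Tug1 (-0.223 and -0.097). The list holds Rian and was chosen after the results were seen, so it is no independent test of this explanation. A genotype effect and a difference between preparations cannot be told apart, since the double-het arrays share 1 genotype by their label.

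Foxa3 and several of its chromosomal neighbours were higher in both groups that carry Foxa3-Cre by their labels, while Mill2, Ccdc61 and Rsph6a were not (log2 -0.06, -0.08 and -0.04). The median log2 difference of the 10 nearest measured neighbours, arrays with the transgene minus those labelled Pdx1-het, was 0.34, at percentile 99.96 of 16976 such windows (5th to 95th percentile -0.052 to 0.07), which argues against a response of Foxa3 alone. Of these neighbours 4 (Mypop, Irf2bp1, Sympk and Dmwd) had all 6 arrays with the transgene above the 3 without it, where chance gives 1.19% of probes and 1.38% of all probes did so. Extra copies of a segment around Foxa3 carried with the transgene may explain these 4, but how the transgene was built is not given in the sources used here, and an effect of the Pdx1-het arrays' own genetic background stays open. Sox9 and Pdx1 also had all 6 arrays above the 3, and the neighbour of Sox9, 2610035D17Rik, had all 6 below.

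Hepatic genes lay higher on the arrays labelled double-het than on both others, with Alb at 859 ± 277 and Afp, which other fetal endoderm also expresses, at 42205 ± 7817 (n = 3 each) against 332 ± 72.3 and 24601 ± 1752 for Sox9-het and 293 ± 50.0 and 30990 ± 3431 for Pdx1-het. Without double-het 3 the hepatic median was 0.33 against Sox9-het and 0.20 against Pdx1-het, with a larger camera adjusted p of 0.0012, and Alb was at 1125 and 572 on double-het 1 and 2 against at most 412 on the 6 other arrays, which argues against double-het 3 alone. Several members were highest on double-het 1. Ahsg was at 424, 192 and 159 on double-het 1, 2 and 3, and Hp at 314, 226 and 177. On Sox9-het 1 these genes were at 243 and 239. Other members did not follow this order, such as Cebpa at 173, 184 and 188. The list kept its camera calls with the preset correlation whichever array was left out, double-het 1 included. The list's calls on all arrays had adjusted p = 0.664 and 0.563 with an estimated correlation. The 12 of 23 hepatic genes that were dim in Sox9-het had a mean pairwise correlation of 0.145 between their residuals within groups, at percentile 98.6 of 1000 random lists (95th percentile 0.097). Liver tissue in varying amounts may contribute, and is a hypothesis tested on the data it came from. A response of these genes to the genotype, in the epithelium itself, was not tested and stays open.

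Other splits of the same arrays were counted for each count of probes or lists. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. Of these, 1 gave as many probes as the labels for double-het minus Sox9-het (57, highest other 1), 1 for double-het minus Pdx1-het (20, highest other 0) and 1 for Pdx1-het minus Sox9-het (43, highest other 0), the real split included. As many lists came from 8 splits for double-het minus Sox9-het (5, highest other 9), 3 for double-het minus Pdx1-het (10, highest other 10) and 3 for Pdx1-het minus Sox9-het (7, highest other 9). Of 100 drawn splits of all 9 arrays, 2 gave as many probes as double-het minus the mean of both single heterozygotes (25, highest other 50) and 2 as many in both double-het comparisons (9, highest other 16), the real split included, a share under 0.05 for both counts. Splits that mix the groups also widen the spread within them, which lowers their counts, so this share alone is not taken to exclude chance. The count of 25 was 3 and 2 without Sox9-het 2 and 3, 7 without Pdx1-het 2 and 10 without double-het 3. The count of 9 was 0 without Sox9-het 2 or Pdx1-het 2 (limma, 1263 and 1179 at an unadjusted p under 0.05). As an overlap it lay inside the range of 100 simulations of unchanged groups on shared arrays (up to 20). Those took sets of the same sizes by rank, whatever their p. The split with 50 and 16 keeps the 3 groups whole and sets Sox9-het in the place of double-het.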
